A study of Mus musculus with 24 samples.

How the data were processed

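RNA from mouse splenic B cells was measured on Affymetrix expression arrays, 1 array per sample. The design has 2 genotypes, B cells deficient for NFATc1 (KO: Nfatc1 with exon 3 flanked by loxP sites, deleted by a Cre recombinase expressed from the Cd79a locus) and control B cells (WT), and 4 times of stimulation with anti-IgM, 0, 3, 8 and 16 h. Each of the 8 groups has 3 biological replicates, which makes 24 arrays. The labels do not say whether arrays of different times that carry the same replicate number came from the same mouse or pool of mice.

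Per the submitters' processing notes the signals were computed with MAS5, with no version given. The deposited values are log2 of these signals: back-transformed values under 50 had 1 decimal within 0.002 signal units in 100% of cases. The mean signal after trimming 2% at each end lay between 499.8 and 499.9 on every one of the 24 arrays, and the lowest value was 0, a signal of 1, which held 0.537% of all values. The authors' scaling was kept and the values were used as deposited. The offset foreseen for a linear file was therefore not applied, and no detection calls were available.

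The array has 45101 probe sets, of which 64 are controls and were left out. The probe table lists 35890 of the 45101, 13 of them controls, 34958 with 1 gene symbol and 932 with several, and 9160 others are not listed. The Entrez identifier of 34754 of the probe sets with 1 symbol matched the gene reference. A probe set was kept when it exceeded the 40th percentile of its own array in at least 3 arrays, which left 33486, of which 26671 had 1 symbol. The probe set with the highest mean represented each gene, which gave 14318 genes. Probe sets with no symbol or several symbols were not used in the comparisons.

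Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 24 arrays, 16 residual degrees of freedom, eBayes with trend, 6.79 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were KO minus WT at each time and averaged over the 4 times, each stimulated time minus 0 h within each genotype, and the 3 differences between the genotypes in these changes, tested singly and together with limma's moderated F-test. Standard errors (SE) are limma's. The number of arrays limits the precision. The fit was tested on simulated data of the same spread, with independent arrays and 200 changed genes. There 58.2% of genes with a 1.5-fold difference and 90.9% with a 4-fold difference were recovered in the averaged contrast, 16.4% and 63.6% at 16 h, and 7.46% and 45.5% in the F-test. Unchanged genes gave 11, 5 and 1 calls. These rates leave out any correlation between arrays of the same genotype and replicate number.

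Contrasts, filter, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names every probe set of Nfatc1, the 12 highest and 12 lowest called genes of the averaged contrast with the same sign at all 4 times, and the 8 genes with the smallest p in the F-test. It also names the 6 highest and 6 lowest called genes at each time and the 8 highest and 8 lowest called genes of each WT stimulation contrast whose groups did not overlap. From these the text names a part. Other genes named are members of the fixed lists, or were chosen after their values were seen. Those chosen so are Dpysl2, Hdhd2 and Pard6g, and Rgs2, P2ry10, Gsn, Tmtc4 and Adamts6 in contrasts other than those in which the rule names them.

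The 32 lists hold 461 genes, of which 400 were tested. Their subjects are NFAT and calcineurin, immediate early genes, activation markers, NF-kB targets, ribosome biogenesis and MYC targets, DNA replication, mitosis, quiescence, apoptosis, glycolysis, cholesterol synthesis, unfolded protein response, plasma cell differentiation, MHC class II, immunosuppressive molecules, cytokines and receptors, interferon response, B cell receptor signalling and heat shock. Marker lists cover marginal zone, follicular, B1 and transitional B cells, T cells, NK cells, macrophages, neutrophils, dendritic cells, erythroid cells, platelets, stromal cells and sex-linked genes. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over 448 tests (32 lists in 14 contrasts), with the result for an estimated correlation given beside it. Of 121 calls, 35 held with the estimated correlation. These tests treat the arrays of the same genotype and replicate number as independent.

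The alternatives were quantile normalization, scaling each array to its median, no filter, a filter at the 60th percentile, every probe set on its own, and replicate number as a fixed block. Others were genotype and replicate number (6 sets of 4 arrays) as a random block, means over the times compared 3 against 3, only the compared groups in the fit, eBayes without trend, a minimum of 1.5-fold, and each array left out in turn. Chosen after the arrays had been examined were offsets at the 25th and 10th percentiles of all signals (23.1 and 6), leaving out the 2 arrays of highest background, and leaving out the 4 arrays with male-type sex-linked expression. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.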

Results

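The data are 24 arrays of RNA from mouse splenic B cells enriched with beads, 12 from mice whose B cells lack NFATc1 (KO) and 12 from control mice (WT). Cells of each genotype were taken at 0, 3, 8 and 16 h of stimulation with anti-IgM, an antibody that crosslinks the B cell receptor, with 3 biological replicates per group. NFATc1 is a transcription factor switched on by calcium and calcineurin downstream of the receptor, and the study asks what it does for how long such cells live, how they work and whether they suppress other cells. All values are log2 of MAS5 signals, with 14318 genes tested, and differences are KO minus WT unless another order is given. The filter level of an array is its 40th percentile, 5.375 to 6.425. Where the dimmer group's mean lay under that level, the difference is given as at least the value left when signals under the level are raised to it. That convention was chosen after the values were seen. Any adjusted p beside such a bound belongs to the difference in the deposited values, not to the bound. The number of arrays limits the precision of each value. Counts of genes at an unadjusted p under 0.05 (limma) are given as background. At 0 h, 3 h and in the genotype by time tests they fell below the share of 0.05 that chance gives.

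The targeted gene itself was measured by 5 probe sets. The brightest Nfatc1 probe set averaged 0.56 higher in KO than WT cells (SE 0.0628, adjusted p = 1.12e-05). It was called at 8 h (0.72, adjusted p = 0.014) and 16 h (0.66, adjusted p = 0.0107). In WT cells its mean was 11.92 at 0 h, 13.22 at 3 h, 12.45 at 8 h and 11.87 at 16 h, and in KO cells 12.16, 13.82, 13.17 and 12.53. The other 4 Nfatc1 probe sets did not pass in the averaged contrast over all probe sets. Their differences were 0.24 (adjusted p = 0.13), 0.11 (adjusted p = 0.916), 0.19 (adjusted p = 0.563) and 0.15 (adjusted p = 0.964). Where these probe sets lie relative to exon 3, the exon that was deleted, is not given, so they check nothing about the labels. Rcan1, a calcineurin inhibitor whose transcription NFAT drives, was lower in KO cells on average (-0.61, SE 0.0916, adjusted p = 0.000519). Its mean went from 8.31 at 0 h to 11.03 at 16 h in WT cells and from 8.41 to 9.33 in KO cells. Of the 18 measured genes of the NFAT and calcineurin list, Nfatc1 was higher, Rcan1 was lower and 16 did not pass in the averaged contrast (3 higher and 2 lower adjusted over the list alone, list adjusted p = 0.673).

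Averaged over the 4 times, KO cells had lower expression of Actn1, which crosslinks actin filaments (-2.23, SE 0.201, adjusted p = 4.39e-07), and of the kinase Sgk1 (-1.41, SE 0.123, adjusted p = 3.59e-07). Also lower were Pdcd1, which encodes the inhibitory receptor PD-1 (by at least 0.768, adjusted p = 0.00135), and Ifng, which encodes interferon gamma (-2.05, SE 0.279, adjusted p = 0.000153). So were the transcription factor Egr2 (-1.03, SE 0.173, adjusted p = 0.002) and Vsir, which encodes the checkpoint molecule VISTA (-1.17, SE 0.15, adjusted p = 6.62e-05). Kcnq5, a voltage-gated potassium channel (-3.31), and Twsg1, which binds bone morphogenetic proteins (-1.10, SE 0.0927), were lower too. Higher in KO cells were Rgs13, which shortens signalling by G proteins (1.32, SE 0.116, adjusted p = 3.59e-07), Jchain, the joining chain of IgM and IgA (1.59, SE 0.193, adjusted p = 3.62e-05), and the scavenger receptor Cd36 (1.12, SE 0.139, adjusted p = 5.32e-05). The complement receptor Cr2 (0.78, SE 0.0868, adjusted p = 9.3e-06), the inhibitory receptor Cd22 (0.78, SE 0.0994, adjusted p = 5.89e-05) and Rgs2, another regulator of G protein signalling (0.78, SE 0.098, adjusted p = 5.89e-05), were higher as well. In total 173 genes passed (limma), 105 higher and 68 lower in KO cells, and 148 of them had the same sign at all 4 times. Of 114 called genes with several probe sets, 22 had a probe set of the opposite sign, and at 16 h 9 of 51 did. Other Actn1 probe sets were lower too (-1.17 and -2.17) but did not pass over all probe sets (limma, adjusted p = 0.607 and adjusted p = 0.127).

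These 173 calls treat the 4 arrays of a genotype and replicate number as independent. With each such set as a random block 46 of the 173 passed, 23 higher and 23 lower. With set means compared 3 against 3, 8 genes passed, 3 higher and 5 lower (Sgk1, Cr2, Tmtc4, Actn1, Rgs13, Pdcd1, Twsg1 and Gsn). Without the 4 arrays of male-type expression 87 passed (56 higher, 31 lower), and with arrays scaled to their medians 86 passed (45 higher, 41 lower), so the excess of higher genes depended on the fit. Of these 87 and 86 genes, 70 and 84 were among the 173. The random block ended the calls of Pdcd1 (adjusted p = 0.0515), Ifi44l (adjusted p = 0.0551) and Apoe (adjusted p = 0.0511), while Rcan1 (adjusted p = 0.0173) and Egr2 (adjusted p = 0.0304) stayed past the threshold. Rgs13, Actn1, Sgk1, Twsg1, Cr2, Gsn and Tmtc4 passed in all 12 settings in which named genes were retested and without any single array.

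**Figure D1:**
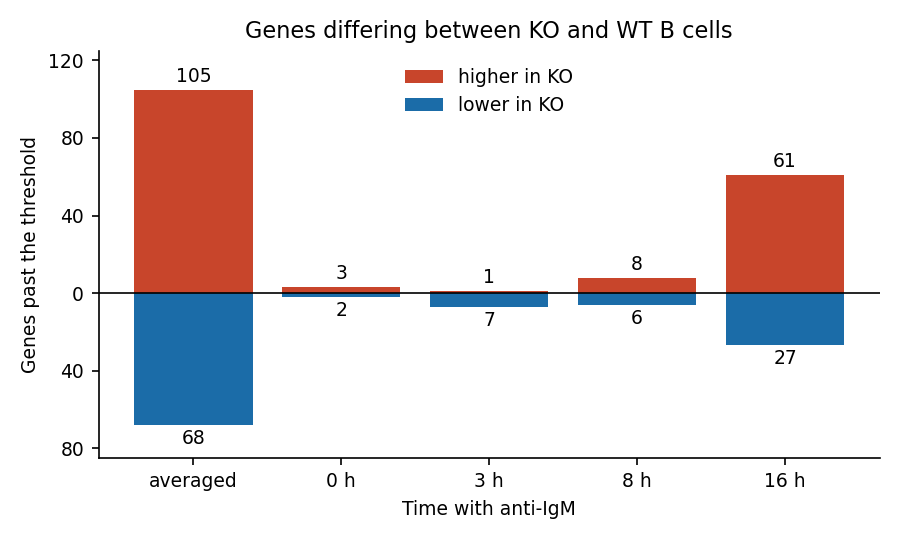
Number of genes higher and lower in KO than WT cells (limma, adjusted p under 0.05) at each time of anti-IgM stimulation and averaged over the times. The counts were 5 at 0 h, 8 at 3 h, 14 at 8 h, 88 at 16 h and 173 for the averaged contrast.

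Markers of B cell subsets differed between the genotypes. All 9 measured markers of marginal zone B cells, a subset resident at the border of the splenic follicle, had positive differences in the averaged contrast, with a mean of 0.40 (SE 0.0589). Cr2, Cd36 and S1pr3 (0.50, adjusted p = 0.0239) were higher and 6 did not pass (4 higher adjusted over the list alone). The list had an adjusted p = 2.57e-07 and an adjusted p = 0.0158 with an estimated correlation. The list was also called at 0 h, before any stimulation (mean 0.43, adjusted p = 1.95e-06, adjusted p = 0.0158 with an estimated correlation). At 0 h 0 of 9 members passed over all genes in limma (2 adjusted over the list alone). Of all 14318 genes 500 had an unadjusted p under 0.05, fewer than chance alone would give. Of 7 B1 cell markers, Plscr1, a phospholipid scramblase (-0.73, adjusted p = 0.00879), and Spn, which encodes CD43 (-0.47, adjusted p = 0.0225), were lower and 5 did not pass (5 lower adjusted over the list alone). The B1 list had a mean of -0.45 and an adjusted p = 9.91e-06, which was 0.0188 as an adjusted p with an estimated correlation. Its mean was -0.576 at 0 h, -0.0555 at 3 h, -0.629 at 8 h and -0.52 at 16 h (SE 0.18 each). The calls of S1pr3, Plscr1 and Spn ended with the random block, with set means compared 3 against 3 and without the 4 arrays of male-type expression. Median scaling ended those of S1pr3 and Spn. That of S1pr3 also ended without trend, without the 2 arrays of highest background and without any 1 of 6 arrays. These were KO replicate 1 at 0 h (adjusted p = 0.0523) and 3 h (adjusted p = 0.0527), KO replicate 2 at 8 h (adjusted p = 0.0524), WT replicate 1 at 0 h (adjusted p = 0.0562) and WT replicate 2 at 0 h (adjusted p = 0.0556) and 16 h (adjusted p = 0.0535). Follicular markers (mean 0.045, list adjusted p = 0.796) and transitional markers (list adjusted p = 0.896) did not pass as lists. Among the follicular markers Fcer2a was higher in limma (0.62, SE 0.121, adjusted p = 0.00738). That call ended with the random block (adjusted p = 0.119) and with set means compared 3 against 3 (adjusted p = 0.204). At 16 h the follicular mean was 0.319 (SE 0.126). Cr2 also stands on the B cell receptor signalling list. The mean of the marginal zone list was 10.93, 10.82 and 10.8 in the 3 sets of KO arrays and 10.28, 10.55 and 10.51 in the 3 sets of WT arrays. This is an order whose exact two-sided p of 0.1 is the smallest that 3 against 3 allows.

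Genes that regulate apoptosis or act in suppression were tested as 2 fixed lists. Of 20 measured apoptosis regulators 0 passed in the averaged contrast in limma over all genes (2 higher and 1 lower adjusted over the list alone, list adjusted p = 0.229). In that contrast 1382 of all genes had an unadjusted p under 0.05. At 3 h the apoptosis list was called, with 16 of 20 positive differences, 0 members past the threshold over all genes or adjusted over the list alone and a median of 0.12 (adjusted p = 0.0334, adjusted p = 0.114 with an estimated correlation). Median scaling ended that call (adjusted p = 0.0835), and 531 of all genes had an unadjusted p under 0.05 in limma at 3 h. Of 16 immunosuppressive molecules Havcr1, which encodes TIM-1, was higher (0.75, SE 0.138, adjusted p = 0.00416), a call that ended with the random block. The other 15 did not pass (2 higher adjusted over the list alone, list adjusted p = 0.387). That list does not hold Pdcd1 and Vsir, which were lower in the same contrast, or Tgfb3, which was higher at 16 h. Il10 differed by -0.70 at 16 h (SE 0.369, adjusted p = 0.792). The list of plasma cell differentiation and class switching had 3 higher members, among them Jchain and the germinal centre factor Bcl6 (0.57, adjusted p = 0.00416), and 1 lower, Spib (-0.36, adjusted p = 0.0159), with a list adjusted p of 0.0759. Its members do not all rise in plasma cells, so these calls give no direction of differentiation. With the random block the adjusted p of Bcl6 was 0.0656 and that of Spib 0.132, neither past the threshold. Several lists were called from small shifts of many members and lost the call with an estimated correlation. Mitosis genes had 21 of 21 positive differences and a median of 0.17 (adjusted p = 0.000224, adjusted p = 0.453 with an estimated correlation), and cholesterol synthesis genes 16 of 16 and a median of 0.18 (adjusted p = 0.000177, adjusted p = 0.369 with an estimated correlation).

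**Figure D2:**
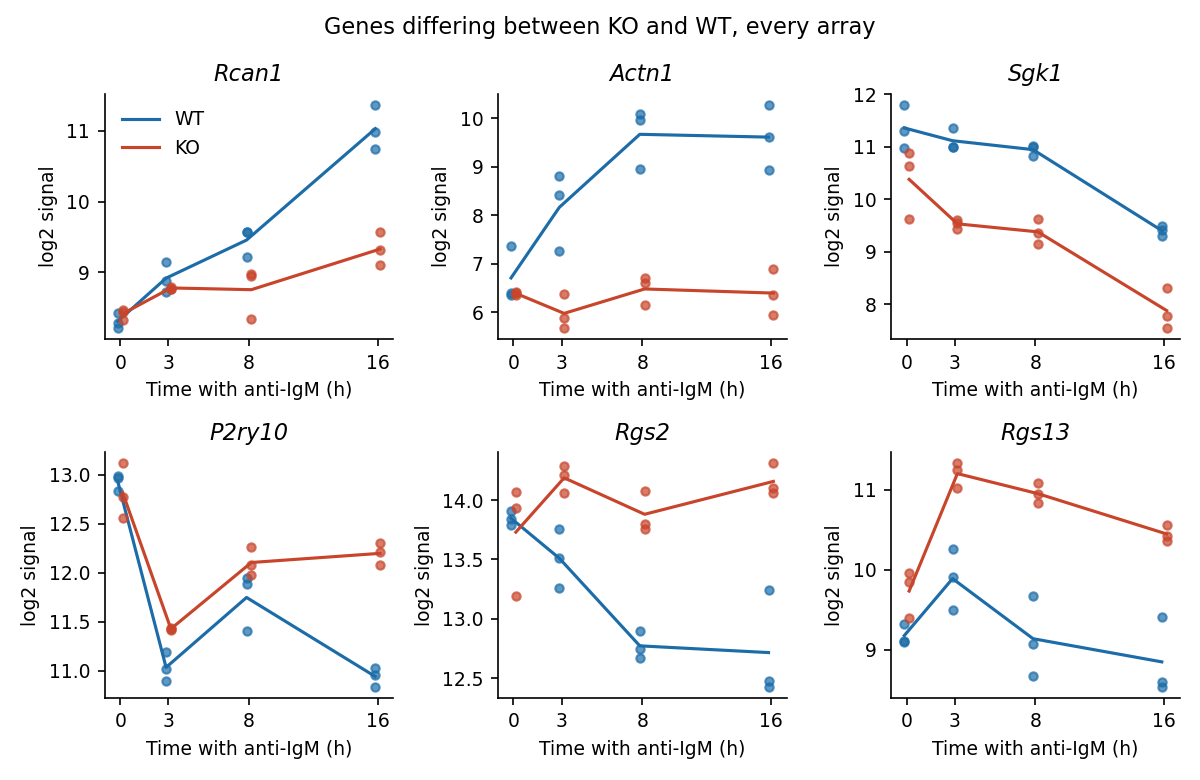
Log2 signal of 6 genes on every array against time of anti-IgM stimulation, 3 arrays per genotype and time, with lines through the group means. Mean Rcan1 reached 11.03 in WT and 9.33 in KO cells at 16 h, and mean Actn1 reached 9.61 in WT and 6.40 in KO cells.

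At 0 h, which compares the cells before stimulation, 5 genes passed, 3 higher and 2 lower in KO cells. In each the 3 KO arrays lay on one side of the 3 WT arrays, an arrangement that chance gives 10% of genes. Calling by p-value favours such genes, so the arrangement adds no support. The interferon-induced gene Ifi44l was higher (8.73 against 2.09, near the floor of the scale, adjusted p = 0.0443), as were Cenps, a centromere protein (1.29, SE 0.22, adjusted p = 0.0258), and Slc66a2 (0.96, SE 0.157, adjusted p = 0.0258). Lower were Ephx1, an epoxide hydrolase (-1.05, SE 0.182, adjusted p = 0.0258), and Lonrf3, at 2.85 in KO and 5.69 in WT cells, both under the filter level (adjusted p = 0.0258). Immediate early genes had a median difference of -0.40 with 0 of 24 passing in limma over all genes (1 lower adjusted over the list alone), beside the 500 genes of any kind at an unadjusted p under 0.05. Their list adjusted p was 2.06e-06 and their adjusted p = 0.354 with an estimated correlation. Heat shock genes had a median of -0.17 with 0 of 10 passing (list adjusted p = 0.00159, adjusted p = 0.278 with an estimated correlation). Neutrophil markers had a mean of -1.02 with 0 of 8 passing (list adjusted p = 0.00516, adjusted p = 0.426 with an estimated correlation). Both lists had 0 members past the threshold adjusted over the list alone. None of the 5 gene calls passed in every setting, and eBayes without trend left 0 genes.

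At 3 h, 8 genes passed, 1 higher and 7 lower in KO cells. Rgs13 was higher (1.31, SE 0.232, adjusted p = 0.0236). Sgk1 (-1.58, SE 0.246, adjusted p = 0.0109), Twsg1 (-1.24, SE 0.185, adjusted p = 0.0109), Actn1 (-2.19, SE 0.402, adjusted p = 0.0316) and the metalloprotease Adamts6 (-1.40, SE 0.224, adjusted p = 0.0111) were lower, as were Tacc2 (by at least 0.957, adjusted p = 0.0316) and Anxa9 (by at least 0.322, adjusted p = 0.0236). For Tacc2 and Anxa9 the adjusted p belongs to the deposited differences of -2.485 and -2.992, which rest on KO values under the filter level. At 8 h, 14 genes passed, 8 higher and 6 lower. Actn1 (-3.19, SE 0.402, adjusted p = 0.000521), Vsir (-1.62, SE 0.3, adjusted p = 0.0272), Sgk1 (-1.56, SE 0.246, adjusted p = 0.0052), Twsg1 (-1.26), Adamts6 (-1.35) and Tmtc4 (-1.24) were lower. Rgs13 (1.81, SE 0.232, adjusted p = 0.000521), Bspry (1.28), Rgs2 (1.11, SE 0.196), Cd22 (1.02), Gsn, which severs actin filaments (0.93), and Cr2 (0.90) were higher. The called genes had groups that did not overlap in 8 of 8 cases at 3 h and 14 of 14 at 8 h, again favoured by the calling. Marginal zone markers were called as a list at both times, with adjusted p = 0.0264 at 3 h and adjusted p = 0.0318 at 8 h with an estimated correlation, and B1 markers at 8 h (adjusted p = 0.0264 with an estimated correlation). At 3 h the count fell to 0 without any 1 of KO replicates 1 and 2 or WT replicates 1 and 2, and at 8 h Rgs13 and Actn1 alone among the named genes passed in all settings and without any single array. With median scaling 3 genes passed at 8 h, 1 higher and 2 lower.

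At 16 h, 88 genes passed, 61 higher and 27 lower in KO cells. In all 88 the groups did not overlap, which calling by p-value favours and so adds no support. Genes of MHC class II antigen presentation, which load and display peptides for helper T cells, were higher. Of 9 measured members 5 passed. H2-DMb2 (1.29, SE 0.17, adjusted p = 0.000255) and H2-DMa (1.17, SE 0.165, adjusted p = 0.000544) encode the chaperone that loads peptides. The others were H2-Oa (0.93, adjusted p = 0.00894) and H2-Ob (0.75, adjusted p = 0.0142), which encode its inhibitor, and H2-Eb1, a chain of the presenting molecule itself (0.67, adjusted p = 0.0298). The 4 members that did not pass had positive differences, with H2-Ab1 at 0.73 (adjusted p = 0.0947), the class II transactivator Ciita at 0.96 (adjusted p = 0.0999), H2-Aa at 0.69 (adjusted p = 0.218) and Cd74 at 0.30 (adjusted p = 0.688). Adjusted over the list alone all 9 were higher. The list mean was 0.83 (SE 0.152) with an adjusted p of 1.58e-21, which was 0.0188 as an adjusted p with an estimated correlation. The list mean was 0.11 at 0 h, 0.19 at 3 h and 0.26 at 8 h. In the averaged contrast the list had 4 of 9 members higher (9 adjusted over the list alone, adjusted p = 8.03e-13), with an adjusted p = 0.05 with an estimated correlation, which did not pass. With the random block in that averaged contrast H2-DMa passed (adjusted p = 0.0388), and H2-Oa (adjusted p = 0.0876), H2-DMb2 (adjusted p = 0.0928) and H2-Eb1 (adjusted p = 0.153) did not. The 88 calls at 16 h, where each set gives 1 array, all held with the random block. Marchf1, a ubiquitin ligase that removes MHC class II from the cell surface, was also higher in KO cells at 16 h (1.94, SE 0.297, adjusted p = 0.00115).

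**Figure D3:**
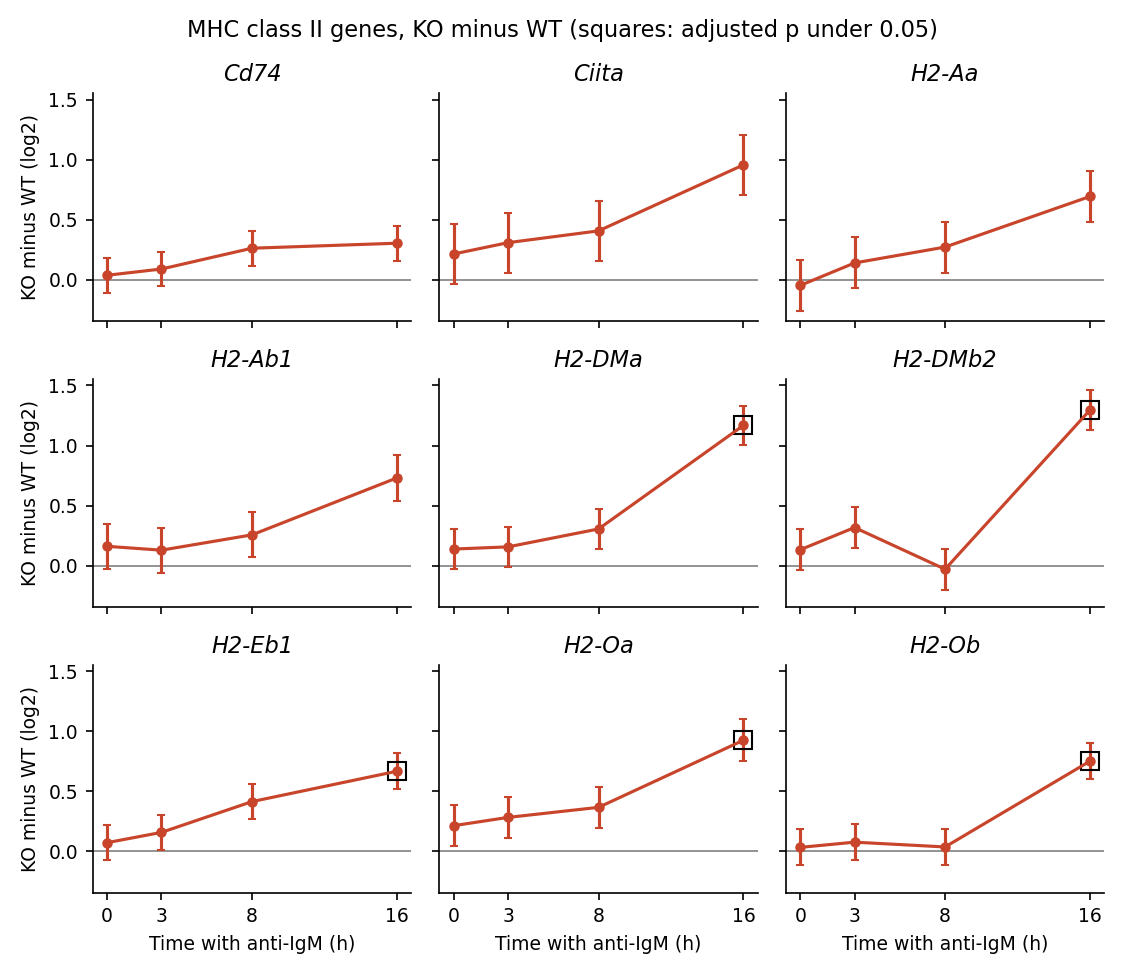
KO minus WT log2 difference with SE of the 9 measured MHC class II genes at each time of anti-IgM stimulation, from limma with 3 arrays per group, with squares where the adjusted p was under 0.05. H2-DMb2 differed by 0.13 at 0 h and 1.29 at 16 h.

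Surface receptors higher in KO cells at 16 h were Fcer2a, which encodes the low-affinity IgE receptor CD23 (1.68, SE 0.242, adjusted p = 0.000612), Cr2 (1.55, SE 0.174, adjusted p = 3.03e-05) and Cd22 (1.41, SE 0.199, adjusted p = 0.000544). The lysophospholipid receptor P2ry10 (1.25, SE 0.137, adjusted p = 3.03e-05), Rgs2 (1.44), Ltb, which encodes lymphotoxin beta (1.01, adjusted p = 0.00556), and the germinal centre transcription factor Bcl6 (0.98, adjusted p = 0.022) were higher too. So were Tgfb3, a member of the TGF-beta family (by at least 1.78, adjusted p = 0.00922), Fndc10 (by at least 1.13), Jchain (1.93, adjusted p = 0.0147), Emid1 (1.87) and Plpp1 (1.81, SE 0.303). Lower were Pdcd1 (-3.29, SE 0.702, adjusted p = 0.0221), Actn1 (-3.21, SE 0.402, adjusted p = 0.000169), Ifng (-2.93, SE 0.557, adjusted p = 0.0107), Rgcc (-2.68), Nkg7, a gene of cytotoxic granules (by at least 0.762), and Epcam (-2.41). Rcan1 (-1.70, SE 0.183, adjusted p = 3.03e-05) and Sgk1 (-1.52) were lower as well. Of 20 B cell receptor signalling genes 3 were higher, Cr2, Cd22 and the phosphatase Ptpn6 (0.52, adjusted p = 0.0241), also 3 adjusted over the list alone. The list had an adjusted p of 0.00114 and an adjusted p = 0.162 with an estimated correlation. DNA replication genes had a median of -0.19 with 0 of 31 passing in limma over all genes or adjusted over the list alone (adjusted p = 0.000378, adjusted p = 0.405 with an estimated correlation). At 16 h 1013 of all genes had an unadjusted p under 0.05. Without KO replicate 2 at 16 h 42 genes passed, without WT replicate 2 at 16 h 43 passed, and without the 4 arrays of male-type expression 36 passed. Actn1, Rcan1, Sgk1, Cr2, Cd22, Fcer2a, Cd36, Rgs2, Rgs13, P2ry10, Plpp1, Tmtc4, H2-DMa and H2-DMb2 passed in all 12 settings and without any single array.

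In WT cells 5486 genes, 38.3% of those tested, were called at 3 h of stimulation (2439 higher, 3047 lower than at 0 h). The counts were 4784 at 8 h (2538 higher, 2246 lower) and 5635 at 16 h (2992 higher, 2643 lower). At 3 h the nuclear receptor Nr4a3 rose by 6.07 (SE 0.44, adjusted p = 1.43e-10), and the high-affinity IL-2 receptor chain Il2ra by at least 4.23. Egr2 rose by 3.49 (SE 0.346), the costimulatory molecule Cd86 by 3.24 (SE 0.219) and the chemokine Ccl4 by 3.04 (SE 0.358). Myc (1.76) and Irf4 (1.75) rose as well. Fos (-5.81, SE 0.408), Jun (-5.11, SE 0.357) and Fosb (-5.02, SE 0.762) fell from high levels at 0 h, where the mean of Fos was 14.65. Of 24 immediate early genes 7 rose and 10 fell at 3 h (9 and 10 adjusted over the list alone, list adjusted p = 0.804). At 16 h Bcat1, which transfers amino groups of branched-chain amino acids (by at least 4.84), Pdcd1 (at least 4.49), Nqo1 (at least 3.8), Cyp1a1 (at least 4.95) and the receptor kinase Axl (at least 4.3) were higher. Ltb (-6.73, SE 0.181) and Marchf1 (-6.34, SE 0.297) were lower. No culture without anti-IgM was measured, so stimulation and time in culture cannot be separated.

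Ribosome biogenesis and MYC targets rose together in WT cells, with 24 of 24 measured genes higher at each time, also 24 adjusted over the list alone. Their medians were 1.83, 1.72 and 1.74 at 3, 8 and 16 h (adjusted p = 1.52e-23 at 3 h, adjusted p = 0.0158 with an estimated correlation). At 3 h Srm, which makes spermidine, rose by 2.72 and Nop56 by 1.74. Of 16 cholesterol synthesis genes 12, 16 and 13 rose, with Cyp51 at 3.22 and Idi1 at 3.71 at 8 h (adjusted p = 2.24e-13 for the list at 8 h, adjusted p = 0.05 with an estimated correlation, not past the threshold). Of 15 glycolysis genes 9, 10 and 10 rose and 2, 2 and 1 fell, with Hk2 at 2.25 at 3 h, Ldha at 2.01 and Slc2a3 at -1.72 at 16 h (adjusted p = 0.0309 at 16 h with an estimated correlation). Of 31 DNA replication genes 5 were higher and 13 lower at 3 h, and 27 were higher and 2 lower at 16 h, also 27 and 2 adjusted over the list alone. Gins2 (2.25), Mcm3 (1.93) and the cyclin Ccnd2 (2.23) rose at 16 h (list adjusted p = 4.85e-09, adjusted p = 0.116 with an estimated correlation). At 16 h 4 of 21 mitosis genes were higher and 2 lower (list adjusted p = 0.781).

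Quiescence genes fell in WT cells. All 17 measured quiescence genes were lower at 16 h, also 17 adjusted over the list alone, with Klf2 at -4.52, the sphingosine phosphate receptor S1pr1 at -3.79 and Tsc22d3 at -5.46 (median -1.90, adjusted p = 5.38e-12, adjusted p = 0.0224 with an estimated correlation). Of 9 MHC class II genes 5, 7 and 9 fell at 3, 8 and 16 h, with H2-DMb2 at -3.36, H2-Eb1 at -1.51 and H2-Aa at -1.11 at 16 h (median -3.13, adjusted p = 2.46e-09, adjusted p = 0.0945 with an estimated correlation). B cell receptor signalling genes fell in 15, 12 and 15 of 20 cases, with the kinase Syk at -3.14 and Cd22 at -2.92 at 16 h (adjusted p = 1.12e-07, adjusted p = 0.026 with an estimated correlation). All 5 follicular markers were lower at 16 h, with Fcer2a at -3.40 (adjusted p = 0.0158 with an estimated correlation), and 6 of 9 marginal zone markers, with Cr2 at -4.08 (adjusted p = 0.0488 with an estimated correlation). On the list of plasma cell differentiation and class switching 11 of 15 genes fell, with Bcl6 at -3.45 (adjusted p = 0.019 with an estimated correlation). Since Bcl6 is a germinal centre transcription factor, this fall does not give a direction of plasma cell differentiation. Among 20 apoptosis regulators 5 rose and 10 fell at 3 h (list adjusted p = 0.362), with the survival gene Bcl2l1 at 1.35, the pro-apoptotic gene Bcl2l11 at 1.70 and the survival gene Bcl2 at -2.62. Immunosuppressive molecules went both ways at 16 h, with 4 of 16 higher, among them Fasl (by at least 2.16), and 5 lower, among them Cd274, which encodes PD-L1 (-3.23), and Cd1d1 (-3.11), with a list adjusted p of 0.565. Scaling each array to its median moved the median change of all genes at 3 h from -0.14 to 0.097 and the count to 2739 higher and 1803 lower, and no list called under both scalings changed direction.

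**Figure D4:**
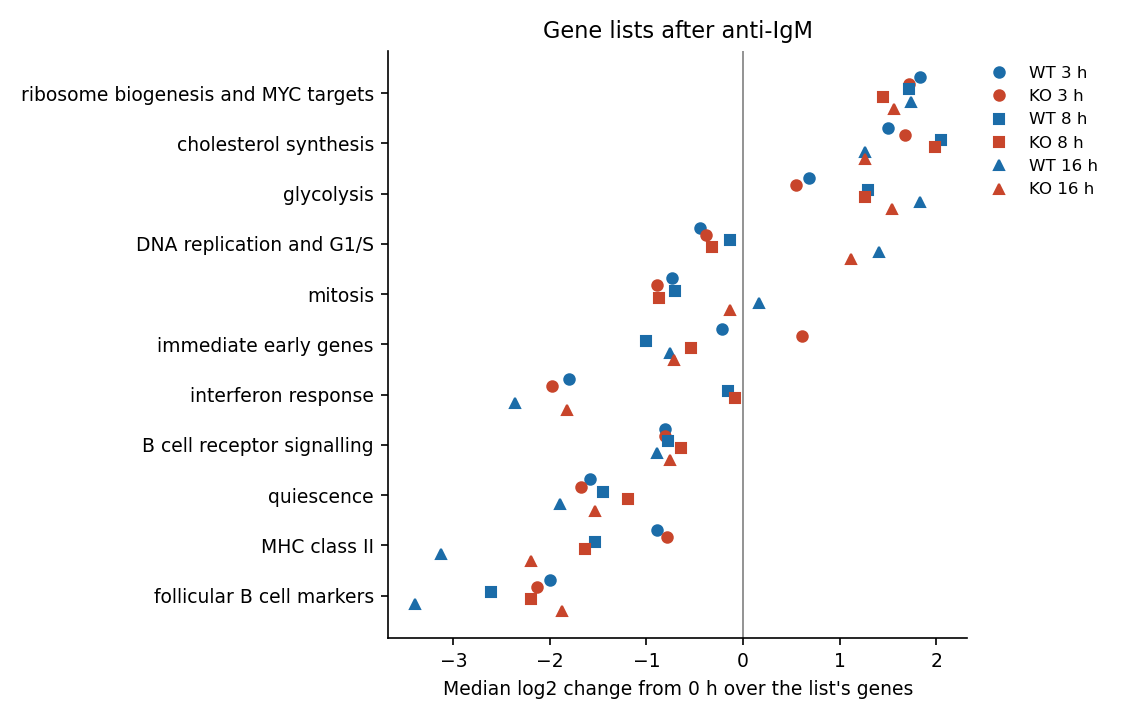
Median log2 change from 0 h of 11 gene lists in WT and KO cells at 3, 8 and 16 h of anti-IgM stimulation. In WT cells at 16 h the median was 1.74 for ribosome biogenesis and MYC targets and -3.13 for MHC class II genes.

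KO cells responded to anti-IgM in much the same genes. In KO cells 5483 genes were called at 3 h (2379 higher, 3104 lower), 4539 at 8 h (2471 higher, 2068 lower) and 5138 at 16 h (2784 higher, 2354 lower). With median scaling 2322 were higher and 2065 lower at 3 h. Of the 5483, 4539 and 5138 genes, 4710, 3839 and 4494 were called in WT cells in the same direction, and 0, 0 and 3 in the opposite direction. At 3 h 2100 genes rose in both genotypes where 405.3 would be shared if the calls were independent. Across genes the changes of the genotypes correlated with a Pearson r of 0.763, 0.71 and 0.761 and a Spearman rho of 0.727, 0.671 and 0.727 at 3, 8 and 16 h, where genes are not independent replicates. The 3 genes called in opposite directions at 16 h were Tgfb3, which fell in WT cells (by at least 0.491) and rose in KO cells (1.72), Ptpn6 (-0.34 and 0.32) and Dpysl2 (0.45 and -0.63). The difference between the changes did not pass for Tgfb3 (adjusted p = 0.175), Ptpn6 (adjusted p = 0.185) or Dpysl2 (adjusted p = 0.181).

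The test of whether the response differed by genotype called 2 genes over the 3 stimulated times together, Rcan1 (adjusted p = 0.0282) and P2ry10 (adjusted p = 0.0332). At 16 h singly, Rcan1 rose less in KO than in WT cells (difference of changes -1.81, SE 0.259, adjusted p = 0.00316), and the changes of P2ry10 (1.37, SE 0.194, adjusted p = 0.00316) and Rgs2 (1.56, SE 0.277, adjusted p = 0.0491) were higher in KO cells. Mean P2ry10 went from 12.93 to 10.94 in WT cells and from 12.82 to 12.2 in KO cells, and mean Rgs2 from 13.85 to 12.72 and from 13.73 to 14.16. At 3 h and 8 h 0 genes passed in limma, with 330 and 446 genes at an unadjusted p under 0.05. Other genes with the smallest p in the joint test did not pass, among them H2-DMb2 (adjusted p = 0.255), Actn1 (adjusted p = 0.261), Cr2 (adjusted p = 0.265), Bcat1 (adjusted p = 0.288) and the kinase Tec (adjusted p = 0.288). The change of the MHC class II list at 16 h was less negative in KO than in WT cells, with a mean difference of changes of 0.73 (SE 0.215). Of its 9 members 0 passed over all genes in limma (624 of all genes had an unadjusted p under 0.05) and 6 adjusted over the list alone. That list had an adjusted p of 2.37e-13, which was 0.0457 as an adjusted p with an estimated correlation. In the joint test Rcan1 and P2ry10 lost their calls with quantile normalization, with median scaling, with eBayes without trend and without the 4 arrays of male-type expression. In the single test at 16 h median scaling ended all 3 calls, and leaving out the 4 arrays of male-type expression ended those of Rcan1 and Rgs2. The Rgs2 call also ended without the filter, without trend, without the 2 arrays of highest background and in 9 of the 12 fits with 1 array left out. The joint calls ended in 8 (Rcan1) and 14 (P2ry10) of the 24 fits with 1 array left out, and that of P2ry10 also without the 2 arrays of highest background. Blocks raised the count of the joint test, to 12 with the random block and 15 with replicate number as a fixed block. With the random block H2-DMb2 (adjusted p = 0.0179), Rgs2 (adjusted p = 0.0192), Actn1 (adjusted p = 0.0167), Cr2 (adjusted p = 0.0345), Bcat1 (adjusted p = 0.0454) and Tec (adjusted p = 0.0435) passed too. With the fixed block Cr2 (adjusted p = 0.0564) and Bcat1 (adjusted p = 0.0527) did not.

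Sets of arrays stood apart in ways other than genotype and time. The 4 arrays of WT replicate 2 had Xist, the transcript of the inactive X chromosome, between 6.17 and 6.62 against 13.27 to 14.54 on the other 20 arrays, and Eif2s3y, on the Y chromosome, between 10.96 and 11.5 against 0 to 5.13. The sex-linked list did not pass between the genotypes (averaged list adjusted p = 0.145). It joins Xist (averaged difference 2.594) with Y-linked genes of the opposite sign (Eif2s3y -2.766, Kdm5d -2.051), which offset each other. The list test therefore does not show that the sexes were balanced, and the 4 male-type arrays were all WT. Erdr1, called higher in KO cells in the averaged contrast (1.19, SE 0.232, adjusted p = 0.00703), had set means of 15.25 and 15.14 in KO replicates 1 and 2, 13.64 in KO replicate 3 and 13.51, 13.54 and 13.40 in the WT sets. Without the 4 arrays of male-type expression its difference was 1.22 (SE 0.282, adjusted p = 0.0579), so the call ended with a wider error over fewer arrays and not with a smaller difference. Macrophage markers had set means of 8.40, 8.28 and 9.17 in KO and 8.06, 9.10 and 8.93 in WT replicates 1, 2 and 3 (averaged list adjusted p = 0.776). KO replicate 2 at 8 h and 16 h had the highest background, with 25th percentiles of 5.26 and 5.45. They also had the highest differences between 3' and 5' signals of Actb, a sign of RNA quality, at 1.08 and 0.914. The same difference for Gapdh, at -0.311 and -0.321, was not highest on them, with -0.2145 in KO replicate 1 at 0 h. The Actb difference averaged 0.466 in WT and 0.485 in KO cells at 0 h. It averaged 0.721, 0.692 and 0.77 in WT and 0.738, 0.767 and 0.701 in KO cells at 3, 8 and 16 h, so RNA quality and stimulation were not separated. The Gapdh difference averaged -0.647 in WT and -0.446 in KO cells at 0 h (standard deviation 0.0335 and 0.2075).

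**Figure D5:**
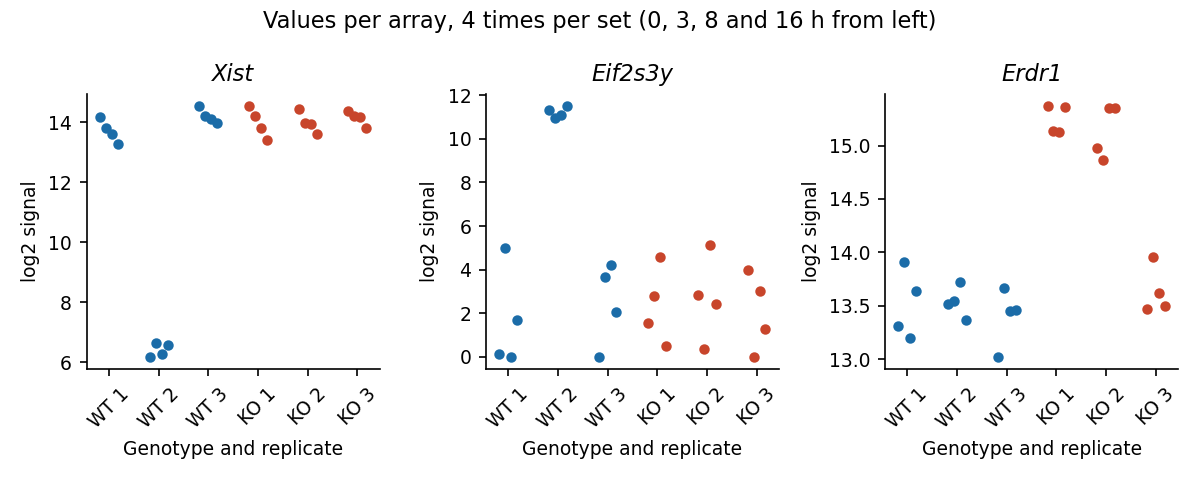
Log2 signal of Xist, Eif2s3y and Erdr1 on each of the 24 arrays, grouped by genotype and replicate number with 4 times each. The set of WT replicate 2 has Xist at 6.62 or less, and KO replicates 1 and 2 have mean Erdr1 values of 15.25 and 15.14.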

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

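The tests of the marginal zone and follicular markers at 0 h were chosen after the results were seen, and so were the fits without the 2 arrays of highest background and without the 4 arrays of male-type expression. Differences between the genotypes in the response to anti-IgM drew attention for Rcan1 (joint test, adjusted p = 0.0282, and at 16 h adjusted p = 0.00316), for P2ry10 (joint test, adjusted p = 0.0332, and at 16 h adjusted p = 0.00316) and for Rgs2 at 16 h (adjusted p = 0.0491). A second Rcan1 probe set differed by -1.69 at 16 h and by -1.61 in the change from 0 h (adjusted p = 0.257 over all probe sets). The MHC class II list drew attention by the same comparison, with an adjusted p = 0.0457 with an estimated correlation. Of 6815 probe sets outside the comparisons because they have no single gene name, 43 passed in the averaged genotype contrast, with differences from -2.35 to 2.03.

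MHC class II genes were higher in KO than WT cells at 16 h by a mean of 0.83 over 9 genes. Array background and the sex of the animals as the whole cause are argued against, since the mean was 0.7 (SE 0.134) without the 2 arrays of highest background and 0.779 (SE 0.182) without the 4 arrays of male-type expression. A response that is weaker or later in KO cells over all genes may account for it in part and stays open. Over 4777 genes the KO minus WT difference at 16 h had a slope of -0.0971 on the WT change from 0 to 8 h, with no array in common, which ranged from -0.121 without KO replicate 1 at 16 h to -0.0567 without KO replicate 2 at 16 h. An effect of NFATc1 on these genes and a delayed response cannot be told apart by this slope, because a delay would also raise genes that fall late.

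Marginal zone markers were higher in KO cells over all times by a mean of 0.40, and the sex of the animals as the cause is argued against by a mean of 0.455 (SE 0.0605) without the 4 arrays of male-type expression. A smaller fall after anti-IgM as the whole cause is argued against by the mean of 0.431 (SE 0.118) at 0 h, before stimulation. A larger share of marginal zone cells among the KO cells could give this pattern and stays open. Follicular markers at 0 h differed by -0.0586 (SE 0.126), a difference too small and too uncertain to show or exclude the small loss that such a shift would bring. Higher expression per cell and a larger share of such cells cannot be told apart in RNA from whole populations.

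For the 173 genes called over all times, sex of the animals and array background as the whole cause are argued against, since the differences had a median of 0.944 of their size without the 4 arrays of male-type expression and 0.971 without the 2 arrays of highest background. Strain variants linked to the targeted alleles stay open and could still act on a few genes: of 317 tested neighbours of Nfatc1 and Cd79a, 4 were called (1.26% against 1.2% of other genes, one-sided Fisher's exact p = 0.533), namely Slc66a2, Pard6g and Hdhd2 beside Nfatc1 (3 of 117, exact p = 0.167) and Apoe beside Cd79a. With whole sets of 4 arrays regrouped, 5 of the 10 splits, the real one among them, called at least as many genes, so chance cannot be excluded. With 10 splits a share under 0.05 was not possible. The highest other called 1336 (KO replicates 1 and 3 with WT replicate 3), several times the real 173, which points to a structure of the sets that is not genotype. Differences between sets may therefore make up part of the 173, and with the sets as a random block 46 passed. That block uses 1 correlation (0.208) for all genes, so the 46 can still hold differences between sets. Erdr1, well above the WT sets in KO replicates 1 and 2 but not 3, is among them (limma with the random block, adjusted p = 0.0217).

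Other splits of the arrays were run for each count. With genotype regrouped among single arrays within each time, 1 of 100 splits, the real one, called as many as 173 genes in the averaged contrast, and the highest other called 24. This excludes chance only if the arrays of a set are independent, and the consensus correlation within the 6 sets was 0.208. For the joint interaction test chance cannot be excluded, since 9 of 100 splits called at least the real 2 genes and the highest other called 47. Nor can it be for the number of lists called in the averaged contrast, where 24 of 100 splits reached the real 7 and the highest other called 14. These splits also break up the sets, so both shares hold only if the arrays of a set are independent. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The number reaching the real count was 2 at 0 h (5 genes, highest other 5) and 1 at 3 h (8, highest other 1), 8 h (14, highest other 13) and 16 h (88, highest other 1). It was 1 for each stimulation contrast, where the highest others called 0, 0 and 1 genes in WT cells and 1, 2 and 4 in KO cells at 3, 8 and 16 h.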

How the results depend on the processing

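The offsets at the 25th and 10th percentiles and the fits without the 2 arrays of highest background or the 4 arrays of male-type expression were chosen after seeing the data. The planned offsets were meant for a linear file and were not run as planned, since flooring at 1 with no offset gives the reported values. The counts of called genes in the 6 stimulation contrasts stayed within 1.5 times the reported ones in every setting but the one that tests all probe sets. The genotype counts and the joint interaction count did not, and no named gene reversed direction in any setting in which named genes were retested. They were not retested with every probe set on its own. There 22 of 114 called genes with several probe sets had one of the opposite sign in the averaged contrast. Probe sets near the floor of the signal limit what can be said of dim genes. The cause was not tested for any change given here, except that testing all probe sets counts more items, a minimum fold counts fewer, and fits with fewer arrays or 3 against 3 have fewer residual degrees of freedom.

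In the averaged genotype contrast (173 reported) 86 genes passed with median scaling, 269 probe sets with all probe sets, 46 genes with the random block, 76 at a minimum of 1.5-fold, 8 with means compared 3 against 3 and 87 without the male-type arrays. At 0 h (5 reported) 2 passed with median scaling, 0 without trend in eBayes (500 at an unadjusted p under 0.05 in the reported limma fit), 1 with only the compared groups, 1 without the high-background arrays and 3 without the male-type arrays. Of these last 3 genes 0 were among the 5 reported. At 3 h (8 reported) the counts were 3 with median scaling, 13 with all probe sets, 2 without trend, 2 with only the compared groups and 0 without the male-type arrays (531 at an unadjusted p under 0.05 in the reported limma fit). At 8 h (14 reported) they were 3 with median scaling, 24 with all probe sets, 23 with the random block, 7 without trend, 5 with only the compared groups, 7 without the high-background arrays and 7 without the male-type arrays. At 16 h (88 reported) they were 43 with median scaling, 48 without trend, 41 with only the compared groups, 42 without the high-background arrays and 36 without the male-type arrays. Testing all probe sets gave 10969, 9509 and 11722 in WT and 10785, 8816 and 10544 in KO cells at 3, 8 and 16 h. The joint interaction test (2 reported) gave 0 with quantile normalization, median scaling, all probe sets, no trend and without the male-type arrays (401 genes at an unadjusted p under 0.05 in the reported limma fit), 12 with the random block and 1 without the high-background arrays. Of the 121 list calls 35 held with the estimated correlation, and the other settings gave 113 to 130. The lists were not retested with the random block or with means compared 3 against 3. The list p-values therefore treat the arrays of a set as independent.

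Replicate number as a fixed block raised the counts to 425 for the averaged contrast, 10 at 0 h, 21 at 3 h, 38 at 8 h, 208 at 16 h and 15 in the joint interaction test. Same-number arrays of the 2 compared groups had correlations of residuals from 0.0159 to 0.222. In no contrast did all 3 exceed 0.1, the limit set for pairing, so the numbers were not treated as pairs. Yet 4 to 6 of the 6 arrays in each contrast correlated best with their own number. Over all groups the median correlation was 0.0765 for the same number and -0.0413 for other numbers, so same-number arrays were somewhat alike.

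With 1 array left out in turn the counts ranged from 135 to 193 in the averaged contrast, 2 to 12 at 0 h, 0 to 7 at 3 h, 6 to 18 at 8 h and 42 to 75 at 16 h. They ranged from 4856 to 5072, 4131 to 4423 and 5041 to 5222 in WT cells and from 4750 to 5097, 3865 to 4222 and 4501 to 4855 in KO cells at 3, 8 and 16 h, and from 0 to 5 in the joint interaction test. Arrays that moved a genotype count by over 1.5 times were at 0 h KO replicate 1 (2 without it), KO replicate 2 (3), KO replicate 3 (12) and WT replicate 3 (3). At 3 h they were KO and WT replicates 1 and 2 (0 without any 1 of them), at 8 h WT replicate 1 (6), and at 16 h KO replicate 2 (42) and WT replicate 2 (43).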

Other observations

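Interferon response genes fell in WT cells after anti-IgM, 12 of 17 at 3 h, 3 at 8 h and 15 at 16 h, with Oas2 at -3.15 and Gbp3 at -2.54 at 3 h and Rtp4 at -3.63 at 16 h (list adjusted p = 3e-05 at 16 h, adjusted p = 0.477 with an estimated correlation). Cytokines, chemokines and their receptors went both ways at 16 h, 9 of 18 lower and 3 higher, with Il10ra at -3.23 and Ltb at -6.73 (adjusted p = 0.0313, adjusted p = 0.0968 with an estimated correlation). Heat shock genes went both ways at 16 h, 4 of 10 higher and 2 lower, with Hspa1b at -6.51 (list adjusted p = 0.617). Activation markers did too, with 7 of 18 higher and 5 lower, among them Cd69 at -2.72 (list adjusted p = 0.889), as did NF-kB targets, with 7 of 16 higher and 4 lower (list adjusted p = 0.506). Of 18 genes of the unfolded protein response 3 were higher and 6 lower (list adjusted p = 0.795), and between the genotypes at 8 h 16 of 18 had positive differences with a median of 0.19 (adjusted p = 0.000341, adjusted p = 0.076 with an estimated correlation).

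Markers of other cells did not pass as lists between the genotypes in the averaged contrast, except erythroid markers. These had 3 of 3 positive differences with a median of 0.91 (adjusted p = 0.0196, adjusted p = 0.0941 with an estimated correlation). The list adjusted p was 0.186 for T cells, 0.619 for NK cells, 0.0693 for neutrophils, 0.876 for dendritic cells, 0.465 for platelets and 0.684 for stromal and endothelial cells. At 3 h NK cell markers had 6 of 6 positive differences and a median of 0.51 (adjusted p = 0.0427, adjusted p = 0.47 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.0569). Neutrophil markers had a mean of -0.99 at 3 h (adjusted p = 0.00542, adjusted p = 0.426 with an estimated correlation). In both lists 0 members passed in limma over all genes or adjusted over the list alone, with 531 of all genes at an unadjusted p under 0.05. Neutrophil marker means were 7.09, 5.75 and 7.69 in KO and 7.10, 7.57 and 7.29 in WT replicates 1, 2 and 3. After 16 h in WT cells 4 of 6 NK cell markers (list adjusted p = 0.116) and 3 of 8 neutrophil markers (list adjusted p = 0.17) were lower.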
